A study of Homo sapiens with 3 samples.

How the data were processed

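Each of the 3 libraries is a ChIP-seq library from BG03 human embryonic stem cells, grown in mTeSR medium on Matrigel, made with an Abcam antibody against H3K27me3, H3K79me2 or Suz12, per the labels. Per the labels' protocols, sonicated chromatin was immunoprecipitated, the DNA was amplified by ligation-mediated PCR over 18 cycles, and inserts of 50 to 200 nucleotides were sequenced. The deposited values are tag positions, 1 per line, with no count, score or normalization. Per the file headers, reads were aligned to hg18 with bowtie with the options -e 70, -k 2, -m 2, -n 2 and -l 36, so reads with more than 2 places in the genome were dropped. The bowtie version is not given in the sources used here. Per the file headers, the H3K27me3 and H3K79me2 libraries came from the same sequencing run and the Suz12 library from another. The run and the antibody therefore cannot be separated for Suz12.

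Each file has a first and a second section of tags. The second section held 8.44% (H3K27me3), 7.55% (H3K79me2) and 8.76% (Suz12) of all tags. It was read as reads with 2 alignments, listed at both places: its totals are even in every library, and its tags in the sequence blocks that the reference repeats identically on chromosomes X and Y stand at the same positions on both, where the first section has none. Only the first section was used, and only on the 22 autosomes. This left 2278192, 5728508 and 6147748 tags for H3K27me3, H3K79me2 and Suz12. At most 1 tag was kept per strand and position, since PCR copies cannot be told from separate fragments; this removed 3.73%, 4.75% and 1.82% of the tags. Tags were moved 75 bp toward the fragment centre, a value set from the insert sizes in the labels. In the H3K79me2 library, pairs of tags on opposite strands were most frequent at an offset of 60 bp (a fragment of 96 bp), and in the other libraries no maximum stood out from the smallest offsets.

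The series design names a whole cell extract as background. It is not analysed here, so each library served as its own background. Tags were counted in 1 kb windows within 10 kb blocks that held at least 1 tag of any library, which gave 2641420 windows. A window was called where its count had a one-sided Poisson p of 1e-09 or less against the library's mean over these windows, which means at least 12 tags for H3K27me3, 16 for H3K79me2 and 17 for Suz12. Called windows at most 2 kb apart were joined into regions. Without the extract, differences in mappability, copy number or chromatin shearing are not removed, and a shared peak can come from any of them. Folds of single regions and windows are over the library's mean density outside the windows called in any library (the background), and folds inside regions of another library are over the density outside all regions. Intervals of folds are 95% Poisson intervals and intervals of shares are 95% Wilson intervals. Both cover counting error only, since tags amplified by PCR are not independent molecules and each antibody has 1 library.

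Overlaps were counted in windows and compared with every circular shift of one set along the joined autosomes, as a description of these libraries and not as a p-value between antibodies. Signal by distance and Spearman correlations of 10 kb windows complete the comparisons. The regions named were set by a rule written before the data were examined: per library the 5 regions with the most tags outside regions that hold windows called in all 3 libraries, the 5 widest regions, and the 5 regions with the most tags called in all 3 libraries. The statement that 28 windows lay near a long stretch without tags was added after seeing the data.

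The caller was tested on simulated counts. With 200 simulated windows per fold size, 81% (H3K27me3), 77.5% (H3K79me2) and 100% (Suz12) were called at 20 times the background, 4.5%, 2.5% and 91.5% at 10 times, and every window at 40 times. No window at the background rate was called. Those counts were drawn from a Poisson distribution, which the threshold also assumes, so this result was near certain. It gives no rate of false calls in real libraries, whose background is uneven. For the overlap, independent simulated sets shared 10 windows where shifts gave 13.38.

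Planned gene results were not made: promoters, gene lists and profiles around gene starts need an annotation of hg18, and the only gene table at hand is of assembly GRCh38.p14. No coordinates were carried between builds. The alternatives tried were the number of tags kept per position, equal depth, looser (1e-06) and stricter (1e-12) thresholds, a local background of 1 Mb, another antibody as background, windows called in all 3 libraries left out, other tag moves (0 and 100 bp) and other window sizes (500 bp, 2 kb and 5 kb; 5 kb and 50 kb for the correlations). Reads with 2 alignments, a background re-estimated from windows not called, and leaving out windows within 1 Mb of long stretches without tags were added after seeing the data. So was a background of windows more than 200 kb from any called window, used only for the ratios in windows called in all 3 libraries. Those ratios were taken with every deposited tag kept. The computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and the plots matplotlib 3.10.9.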

Results

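Chromatin of human embryonic stem cells of the BG03 line, grown without feeder cells, was immunoprecipitated with 3 antibodies and the recovered DNA was sequenced (ChIP-seq). The first antibody recognises trimethylated lysine 27 of histone H3 (H3K27me3), the mark of genes silenced by Polycomb proteins. The second recognises Suz12, a core subunit of Polycomb repressive complex 2 (PRC2), the enzyme complex that places that mark. The third recognises dimethylated lysine 79 of histone H3 (H3K79me2), which DOT1L places over the transcribed part of active genes. There was 1 library per antibody, so no difference between antibodies could be set against a replicate, and no p-value is given between them. Except where resampling is named, intervals are 95% intervals of counting error only. The libraries held 2364839 (H3K27me3), 5939595 (H3K79me2) and 6413828 (Suz12) tags with a single place in the genome, of which 2193145, 5456204 and 6035918 distinct autosomal tag positions were analysed. All positions are in the hg18 build.

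The 3 proteins and marks covered the genome very differently. H3K79me2 filled 9007 regions with 56.03 Mb in total, while H3K27me3 was enriched in 1668 regions with 7.3 Mb and Suz12 in 2236 regions with 6.17 Mb. H3K79me2 regions were also the widest, with a median of 3 kb (middle 50% of regions from 1 to 7 kb) and 579 regions of at least 20 kb. H3K27me3 regions had a median width of 2 kb and 58 reached 20 kb, and Suz12 regions had a median of 1 kb and 14 reached 20 kb. Inside called 1 kb windows, H3K79me2 tags were 66.5-fold denser than outside the windows called in any library, H3K27me3 tags 46.8-fold and Suz12 tags 14.2-fold. The H3K79me2 windows held 56.4% of that library's tags (Wilson interval 56.36 to 56.44%), the H3K27me3 windows 10.85% (10.81 to 10.89%) and the Suz12 windows 2.89% (2.88 to 2.9%). To be called, a 1 kb window needed a density of 16.4 times the rate outside called windows in the H3K27me3 library, 17.5 times in the H3K79me2 library and 7.8 times in the Suz12 library. At equal depth, the H3K79me2 library gave 30965 called windows in place of 50606 and the Suz12 library 2044 in place of 5602.

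The strongest H3K27me3 regions were long, nearly unbroken domains. The widest lay on chromosome 12 from 52607001 to 52742000 (135 kb), with 6779 H3K27me3 tags, 68.7-fold over the rate outside called windows (67.1 to 70.4), and 132 of its windows called. Next in width were chromosome 7 from 27098001 to 27222000 (124 kb, 80.1-fold), chromosome 17 from 43973001 to 44081000 (108 kb, 83.2-fold) and chromosome 2 from 176651001 to 176714000 (63 kb, 64.5-fold). The fifth, on chromosome 17 from 44150001 to 44189000 (39 kb), held H3K27me3 at 63.1-fold. Denser still were a 21 kb region on chromosome 19 from 1697001 to 1718000, at 119.2-fold (113.8 to 124.8), and a 29 kb region on chromosome 17 from 75378001 to 75407000, at 90.0-fold (86.0 to 94.2). Gene names are not attached to these positions, since no annotation of hg18 was used here.

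The H3K79me2 regions with the most tags were of a similar or greater length. The region on chromosome 6 from 15352001 to 15595000 was both the widest (243 kb) and the one with the most tags, 40133, or 180.5-fold over the rate outside called windows (178.7 to 182.3). An 84 kb region on chromosome 3, from 32829001 to 32913000, had the highest density of the named H3K79me2 regions, 259.9-fold (256.3 to 263.6). The regions on chromosome 8 from 128875001 to 129054000 (179 kb), chromosome 16 from 87901001 to 88085000 (184 kb) and chromosome 10 from 126683001 to 126839000 (156 kb) had H3K79me2 at 138.8-fold, 119.9-fold and 96.8-fold. Among the widest were also chromosome 1 from 64011001 to 64177000 (166 kb, 70.3-fold) and chromosome 15 from 97010001 to 97171000 (161 kb, 51.3-fold). In these 7 regions H3K27me3 lay between 1.6-fold and 2.0-fold and Suz12 between 1.5-fold and 1.7-fold, and no window in them was called for either.

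**Figure D1:**
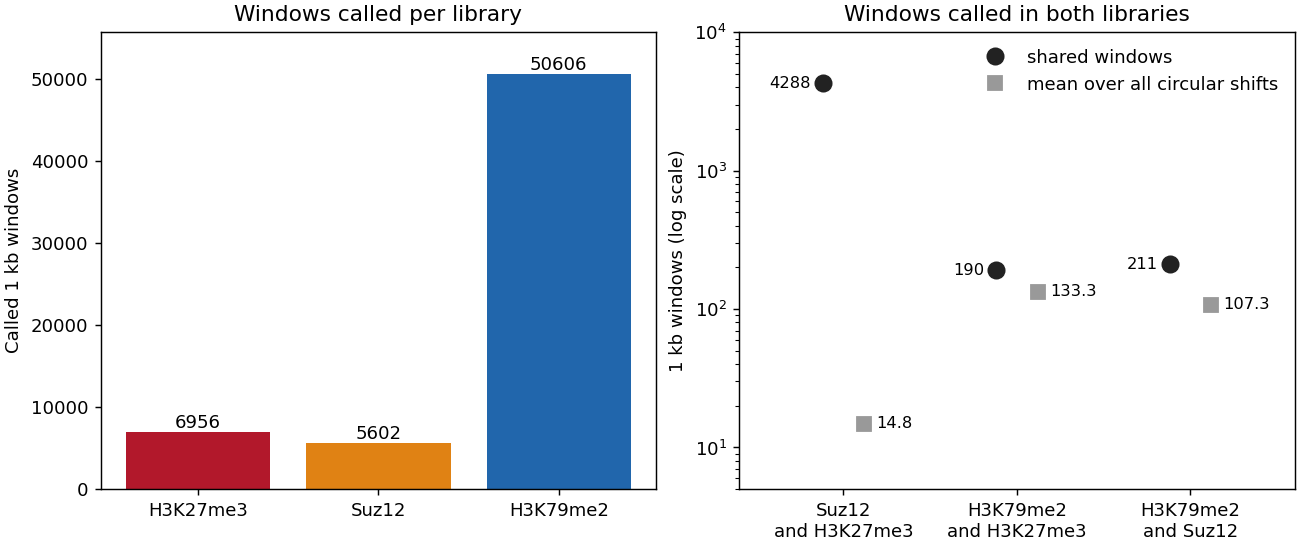
Left, number of called 1 kb windows per library (bars; linear axis from 0). Right, number of windows called in both libraries of each pair (circles) and the mean number over all circular shifts of one set along the autosomes (squares), on a log axis; Suz12 and H3K27me3 shared 4288 windows where shifts gave 14.8 on average.

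Because PRC2 places H3K27me3, the first comparison asked how far Suz12 and H3K27me3 occupied the same sites. They largely did. Of the 5602 Suz12 windows, 4288 (76.54%, Wilson interval 75.42 to 77.64%) were also H3K27me3 windows, and these made up 61.64% (60.5 to 62.78%) of the 6956 H3K27me3 windows. Sliding one set along the autosomes gave 14.8 shared windows on average, so the observed number was 291-fold higher, and no other of the 2641420 shifts reached it (the highest gave 3619). Shifts of 20 to 200 kb, which keep the sets in the same neighbourhoods, gave 45 to 549. The observed number was 24.47 times their mean of 175.2. Wide domains were shared almost without exception: 379 of the 386 H3K27me3 regions of at least 5 kb held a Suz12 window, and all 313 Suz12 regions of at least 5 kb held a H3K27me3 window.

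Regions of a single 1 kb window offer just 1 place for a call of the other library, so their shares cannot be set against those of wide domains. Of such H3K27me3 regions, 46.4% held a Suz12 call, and of the single-window Suz12 regions 32.9% held a H3K27me3 call. Windows called for only one of the pair still carried tags of the other. In the 2668 H3K27me3 windows without a Suz12 call, Suz12 tags were 4.63-fold over background (4.58 to 4.69), and in the 1314 Suz12 windows without a H3K27me3 call, H3K27me3 tags were 8.68-fold (8.49 to 8.87). With every library thinned to the depth of the H3K27me3 library, 1943 windows were shared, 95.06% of the Suz12 windows then called and 27.93% of the H3K27me3 windows.

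Across whole regions, Suz12 tags were 11.14-fold denser inside H3K27me3 regions than outside all regions (11.09 to 11.19), and H3K27me3 tags were 44.94-fold denser inside Suz12 regions (44.74 to 45.15). Both fell away within a few kb. Suz12 tags were 3.87-fold over background 1 kb from the nearest H3K27me3 window, 2.08-fold at 2 kb and 1.39-fold at 6 to 10 kb. The largest Suz12 regions lay inside the largest H3K27me3 domains. Suz12 reached 20.5-fold (19.7 to 21.4) on chromosome 7 from 27145001 to 27200000 (55 kb), where H3K27me3 stood at 103.7-fold. On chromosome 17 from 44022001 to 44070000 (48 kb) Suz12 stood at 15.8-fold, and on chromosome 2 from 176670001 to 176710000 (40 kb) at 14.1-fold. A pair of separate Suz12 regions, from 52629001 to 52656000 (27 kb, 16.7-fold) and from 52659001 to 52705000 (46 kb, 14.1-fold), lay within the chromosome 12 domain. The dense H3K27me3 region on chromosome 19 had Suz12 at 20.2-fold, with 20 of its 21 windows called.

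**Figure D2:**
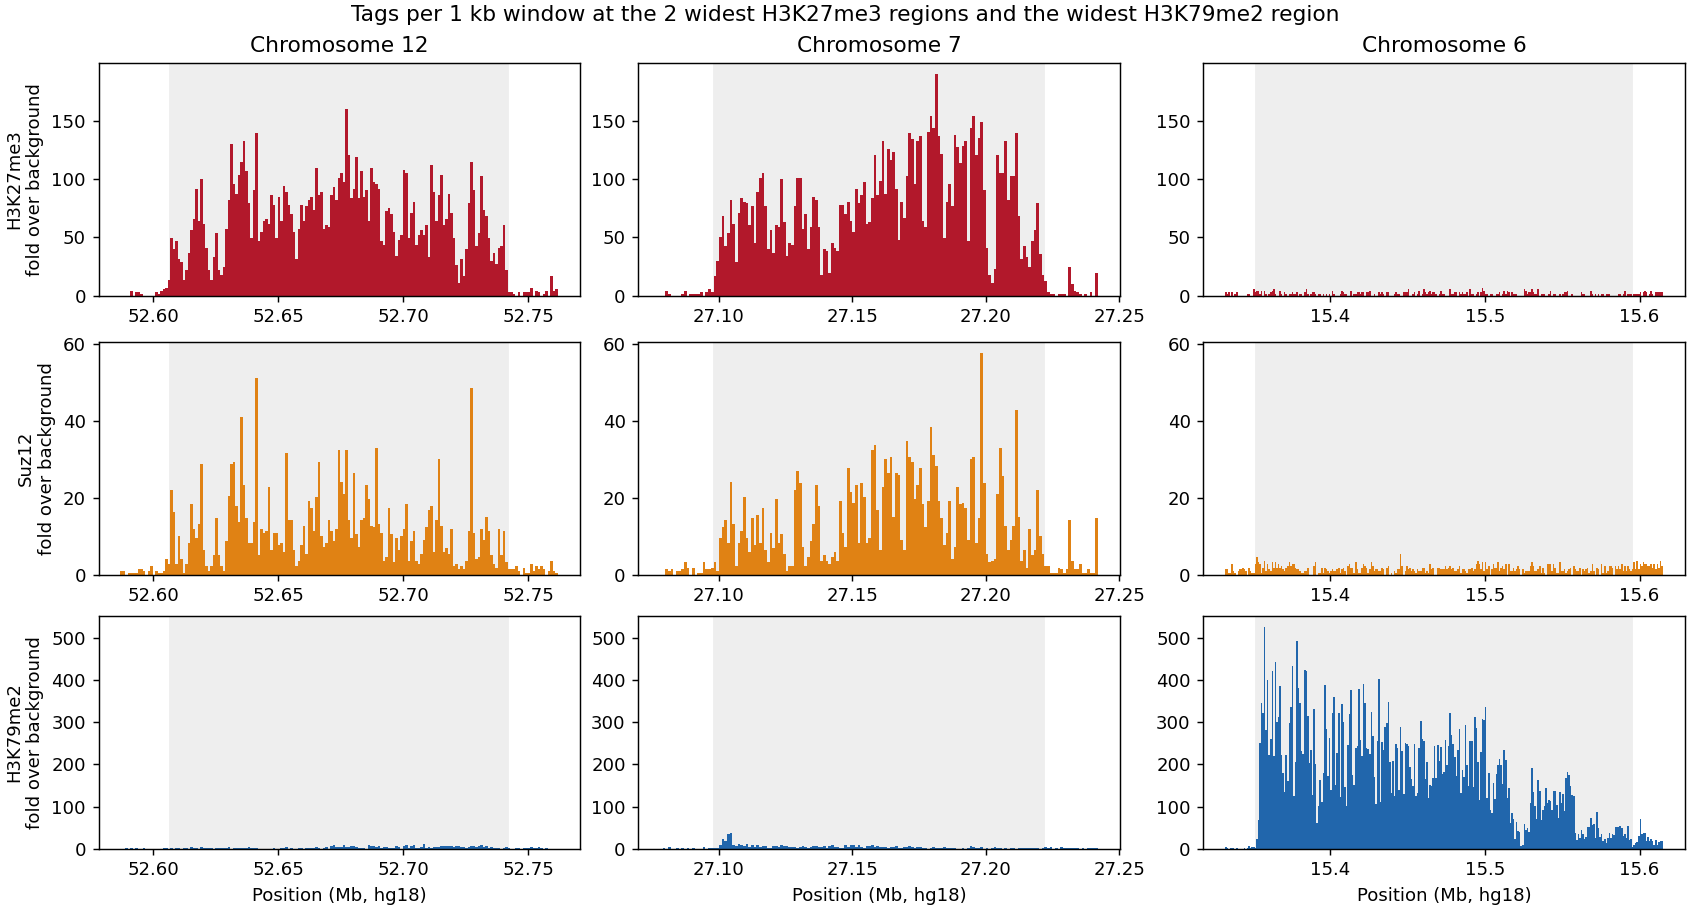
Tags per 1 kb window as fold over each library's rate outside the windows called in any library (linear axes from 0, the same scale along each row of panels) at the H3K27me3 regions on chromosomes 12 and 7 and the H3K79me2 region on chromosome 6, with 20 kb on either side; the region is shaded and positions are in Mb (hg18). H3K27me3 and Suz12 fill the first and second region, at 68.7-fold and 12.2-fold over the chromosome 12 domain, and H3K79me2 fills the third at 180.5-fold.

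The second comparison set a mark of transcribed genes, H3K79me2, against the Polycomb mark H3K27me3. Few windows were called for both, but no fewer than shifted sets gave on average. They numbered 190, which is 2.73% (2.37 to 3.14%) of the H3K27me3 windows and 0.38% (0.33 to 0.43%) of the H3K79me2 windows. Of all windows, 1.916% were called for H3K79me2. In the simulation, 2.5% of windows at 10 times the H3K79me2 background were called, so weaker H3K79me2 in H3K27me3 windows goes uncounted. Of the 1668 H3K27me3 regions, 97 (5.8%, 4.8 to 7.0%) held a H3K79me2 window. Shifted sets gave 133.3 on average, so the observed number was 1.43 times that mean, and 4.746% of all shifts gave 190 or more. Shifts of 20 to 200 kb, which keep the sets in the same neighbourhoods, gave 58 to 239.

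Most windows called for H3K79me2 and H3K27me3 were called for Suz12 too. There were 146 windows called in all 3 libraries, in 91 regions, and 44 others. Of all H3K27me3 windows, 61.64% were also Suz12 windows, so a majority was likely from that share alone. With all libraries at the same depth, 80 windows were shared where 81.9 were expected, and with tags of 2 alignments added, 289 where 140.6 were expected. Of the 5 widest H3K27me3 regions, which were named whatever H3K79me2 showed there, 4 held no window called for H3K79me2. Its tags in them lay at 2.9-fold (chromosome 12), 5.5-fold and 0.8-fold (chromosome 17) and 2.0-fold (chromosome 2) over the rate outside called windows. The genome-wide mean of 2.26-fold includes the called H3K79me2 windows, which held 56.4% of its tags. It is therefore no level for regions without a call. In the chromosome 7 domain, at 4.4-fold, 4 of 124 windows were called for H3K79me2, and the map of that region shows them at its low-coordinate end.

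H3K79me2 was lower 2 to 10 kb away from H3K27me3 windows than 101 to 200 kb away. Over the whole genome H3K79me2 tags averaged 2.26-fold over that library's background, its rate outside all called windows. They stood at 2.02-fold 2 kb from the nearest H3K27me3 window (1.97 to 2.07), 2.03-fold at 3 to 5 kb (2.0 to 2.06), 1.85-fold at 6 to 10 kb (1.83 to 1.87) and 3.12-fold at 101 to 200 kb (3.11 to 3.13). In the H3K27me3 windows themselves the value was 2.94-fold (2.9 to 2.99), or 1.99-fold (1.96 to 2.03) in those without a H3K79me2 call. The second value leaves called windows out, so it compares with the background, over which it was raised, and not with the 2.26-fold mean. Conversely, H3K27me3 tags were 1.64-fold over background (1.62 to 1.65) in H3K79me2 windows without a H3K27me3 call.

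**Figure D3:**
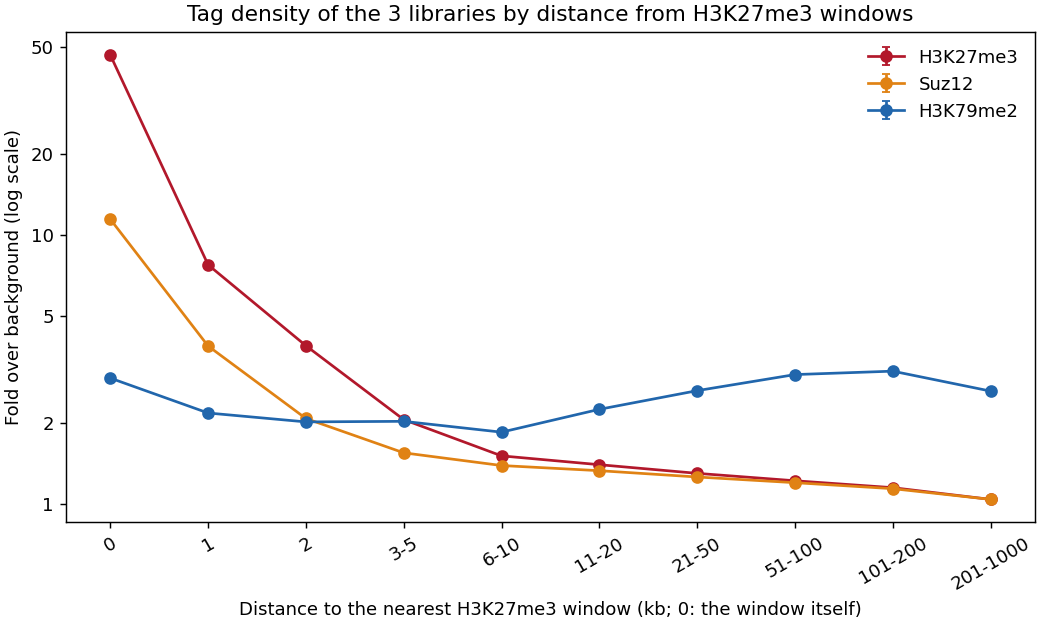
Mean tag density of the 3 libraries as fold over each library's rate outside the windows called in any library (log axis) by distance in kb from the nearest H3K27me3 window; error bars are 95% counting intervals and are smaller than most points. Suz12 falls from 11.47-fold to 1.39-fold by 6 to 10 kb, where H3K79me2 is at its lowest, 1.85-fold.

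The third comparison, of H3K79me2 with Suz12, also gave few shared windows, though further above the mean over shifts. The windows called for both numbered 211, or 3.77% (3.3 to 4.3%) of the Suz12 windows and 0.42% (0.36 to 0.48%) of the H3K79me2 windows. The mean over shifts was 107.3, and 0.053% of shifts gave as many, so the observed number was 1.97 times that mean. Shifts of 20 to 200 kb gave 57 to 194, and the observed number was 1.68 times their mean of 125.5. Of the 211 windows, 146 were called in all 3 libraries and 65 were not. With all libraries at the same depth, 42 were shared where 24.1 were expected, 2.05% of the Suz12 windows then called. At a looser threshold the overlap grew to 815 windows, 8.15% of the Suz12 windows then called. H3K79me2 tags were denser next to Suz12 sites than next to H3K27me3 sites: against a genome-wide mean of 2.26-fold, they stood at 4.16-fold 1 kb from the nearest Suz12 window (4.1 to 4.22) and at 2.18-fold 1 kb from the nearest H3K27me3 window (2.13 to 2.23). In the Suz12 regions as a whole H3K79me2 was at 3.71-fold, and in the H3K27me3 regions at 3.0-fold, over its density outside all regions. At the looser threshold these were 7.31-fold and 3.32-fold, and at the stricter one 3.21-fold and 2.83-fold. A Suz12 window was called from 7.8 times the rate outside called windows and a H3K27me3 window from 16.4 times. What weaker Suz12 calls add to the difference was not tested.

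The 146 windows called in all 3 libraries were spread over 91 regions. The 5 such regions with the most tags lay on chromosome 6 from 58884001 to 58888000, chromosome 2 from 132743001 to 132752000, chromosome 12 from 112388001 to 112398000, chromosome 1 from 121186001 to 121187000 and chromosome 20 from 26136001 to 26139000. The single window on chromosome 1 stood at 476.4-fold for H3K27me3, 297.2-fold for H3K79me2 and 236.3-fold for Suz12. These values depend on how repeated positions are treated: with every deposited tag kept they were 832.7-fold, 476.9-fold and 622.9-fold, and Suz12 in the regions on chromosomes 6 and 20 also rose by over 1.5 times. Adding tags with 2 alignments raised the regions on chromosomes 1 and 6 by over 1.5 times in all 3 libraries. The region on chromosome 2 rose by over 1.5 times for H3K27me3 and Suz12. The region on chromosome 12 had H3K27me3 at 85.3-fold (78.7 to 92.3), H3K79me2 at 29.6-fold (26.2 to 33.4) and Suz12 at 13.2-fold (11.7 to 14.8). Of the 146 windows, 28 (19.2%) lay within 1 Mb of a stretch of at least 500 kb without any tag, as did 1.31% of all windows.

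Without any threshold, tag counts in 264142 windows of 10 kb correlated most between Suz12 and H3K27me3 (Spearman's rho 0.625), less between H3K79me2 and Suz12 (0.572) and least between H3K79me2 and H3K27me3 (0.487). These are correlations across windows, which are not independent replicates. They depend on the depth: with all libraries at the same depth the values were 0.526, 0.391 and 0.393, so the order of the lower pair was lost.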

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

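The tests of this part were chosen after the result was seen. Mitochondrial tags and tags with 2 alignments were not used in the comparisons, and are given here because they hold a signal in data outside them; no control library sets a level for either. The mitochondrial genome took 0.0895% of the single-alignment tags of the H3K27me3 library (2117 tags, 95% Wilson interval 0.0858 to 0.0934%), 0.0168% of the H3K79me2 library (999 tags, 0.0158 to 0.0179%) and 0.166% of the Suz12 library (10645 tags, 0.1628 to 0.1691%). Tags with 2 alignments were 15.42-fold denser inside the called windows of their own library than outside for H3K27me3, 16.16-fold for H3K79me2 and 10.26-fold for Suz12. Without the windows called in all 3 libraries these values were 9.39-fold, 15.89-fold and 5.89-fold.

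The mitochondrial share could follow the share of unenriched DNA in each library, since mitochondrial DNA has no histones. Per 1000000 tags outside the library's called windows there were 1083 mitochondrial tags for H3K27me3 (1037 to 1130), 420 for H3K79me2 (394 to 447) and 1816 for Suz12 (1782 to 1851), so the highest was still 4.32 times the lowest, which argues against this as the whole cause. The sequencing run alone does not account for the H3K27me3 and H3K79me2 libraries, which came from the same run and differed 2.58-fold. That factor is likely too high, since tags outside called windows include weak H3K79me2 signal. More than 200 kb from any called window, tag density was 0.63 times the background for H3K79me2 and 0.84 times for H3K27me3. Mitochondrial tags were also counted with repeated positions kept, unlike the tags outside called windows. The amount of carried-over DNA in each precipitation stays open, and no biological explanation was tested.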

How the results depend on the processing

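Adding tags with 2 alignments, re-estimating the background and leaving out windows near long stretches without tags were chosen after the data were seen. Suz12 and H3K27me3 shared windows far above the mean over shifts under every alternative run, from 119-fold (5 kb windows) to 401-fold (500 bp windows), and the share of Suz12 windows inside H3K27me3 windows ran from 58.52% (looser threshold) to 95.06% (equal depth). The overlap of H3K79me2 with H3K27me3 moved both ways: the log2 of shared over expected windows was 0.51, 1.04 with tags of 2 alignments added (289 shared, 140.6 expected), -0.03 at equal depth and -1.56 without windows called in all 3 libraries. With Suz12 it was 0.98, rose to 1.86 at the looser threshold and turned only without those windows, to -0.68, or to no shared window under the rule on the other antibody given next. Every window called in all 3 is a shared one, so leaving them out forces these drops and shows no avoidance; the cause of the other changes was not tested. In kb called for both, in the order H3K79me2 and H3K27me3, H3K79me2 and Suz12, the alternatives gave 80 and 42 at equal depth (with Suz12 and H3K27me3 at 1943), 44 and 65 without windows called in all 3, 289 and 353 with tags of 2 alignments, 297 and 815 at the looser threshold, and 114 for H3K79me2 and Suz12 at the stricter one. Requiring 3 times the density of the other antibody gave 0 and 0, which that rule forces. With 500 bp, 2 kb and 5 kb windows the kb in both were 83.5, 360 and 895 for H3K79me2 and H3K27me3, 68, 626 and 2045 for H3K79me2 and Suz12, and 2459.5, 6952 and 11980 for Suz12 and H3K27me3. The kb called for Suz12 were 2044 at equal depth, 10002 at the looser threshold and 3123, 9282 and 17300 with those windows. H3K79me2 had 30965 kb at equal depth and 97775 kb with 5 kb windows, where H3K27me3 had 15320 kb. Wider windows hold more tags, so lower folds pass the threshold. Spearman's rho for Suz12 with H3K27me3, H3K79me2 with Suz12 and H3K79me2 with H3K27me3 was 0.526, 0.391 and 0.393 at equal depth, 0.515, 0.479 and 0.39 in 5 kb windows, and 0.846, 0.707 and 0.656 in 50 kb windows. Most folds inside regions of another library moved beyond their counting intervals. The exceptions were H3K27me3 in Suz12 regions with every tag kept and H3K27me3 in H3K79me2 regions at the looser threshold. All folds stayed above 1. For H3K79me2 that says little, since its genome-wide mean was already 2.26-fold over its rate outside called windows. At equal depth, H3K27me3 was 65.83-fold in Suz12 regions and 1.78-fold in H3K79me2 regions, Suz12 11.02-fold in H3K27me3 and 1.72-fold in H3K79me2 regions, and H3K79me2 2.59-fold in H3K27me3 and 3.09-fold in Suz12 regions. In that same order the folds were 51.51, 1.78, 11.72, 1.71, 2.83 and 3.21 at the stricter threshold, and 44.63, 1.61, 10.83, 1.62, 2.22 and 2.84 without windows called in all 3. At the looser threshold H3K27me3 in Suz12 regions was 30.51-fold, Suz12 10-fold in H3K27me3 and 1.68-fold in H3K79me2 regions, and H3K79me2 3.32-fold in H3K27me3 and 7.31-fold in Suz12 regions. With every deposited tag kept, H3K27me3 in H3K79me2 regions was 1.82-fold, Suz12 11.56-fold in H3K27me3 and 1.75-fold in H3K79me2 regions, and H3K79me2 3.17-fold in H3K27me3 and 4.1-fold in Suz12 regions. Each main result was counted once per alternative. Of these values, 78 stayed within the interval of the main value or, for counts, within 1.5 times of it, and 66 moved further. Of the 72 folds of the 24 named regions, 62 stayed between 0.69 and 1.38 times the reported value. The 10 others moved by over 1.5 times: 9 belong to the regions called in all 3 libraries on chromosomes 1, 2, 6 and 20, where keeping more tags per position or adding tags with 2 alignments raised them by up to 2.64 times (Suz12 on chromosome 1), and 1 is the low H3K79me2 fold of the chromosome 19 region, 1.2 reported and 0.8 at equal depth. The alternatives planned for promoters and gene lists were not run, since no hg18 annotation was used. Libraries carried no replicate numbers, so no paired analysis was possible because each antibody had 1 library.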

Other observations

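The tests of this part were chosen after the result was seen, except the test of tags at one end of H3K79me2 regions and the test of regions meeting in 1 window. Wide H3K79me2 regions were one-sided, which fits a mark that is strongest near the start of a transcribed gene, although no gene was placed on these regions. In the 579 H3K79me2 regions of at least 20 kb, the heavier side of the region held a median of 67.1% of the tags (middle 50% of regions from 61.4 to 72.6%), against 54.5% after shuffling the windows within each region. In 435 of them (75.1%) the value was above 95% of 1000 shuffles. The 58 H3K27me3 regions of that width were close to even, with a median of 55.8% (54.0 to 58.2%) against 53.2% after shuffling, and 10 of them (17.2%) were above 95% of shuffles. Windows next to each other resemble each other, so shuffles understate chance for both marks; the contrast between the marks does not rest on the shuffles alone.

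A hypothesis was that Suz12 is gathered in the middle of H3K27me3 regions more than H3K27me3 itself. The predicted higher ratio for Suz12 was not seen. The regions and their edges were set by H3K27me3 calls, which shapes the H3K27me3 ratio, so the comparison cannot decide the question. Both were denser in the middle than in the outer parts, Suz12 at 12.32-fold and 11.05-fold and H3K27me3 at 57.46-fold and 47.37-fold. In the 386 regions of at least 5 kb, the median ratio of excess tags in the middle to those in the outer parts was 1.17 for Suz12 and 1.24 for H3K27me3, a difference of -0.07, and Suz12 was the more concentrated in 168 regions (43.5%).

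The windows called in all 3 libraries were weighed in separate parts, the 28 near long stretches without tags and the 118 others. Unlike the main results, the ratios of folds here used every deposited tag, since keeping 1 tag per position can saturate dense windows. Extra copies of repeated DNA that hg18 lacks would by themselves raise every library alike; for the 28 windows this cannot be told apart, since the ratio of the H3K27me3 fold to the H3K79me2 fold was 1.64 (middle 50% of windows from 1.35 to 1.84) over the rate outside called windows but 1.23 (1.02 to 1.38) over that of windows more than 200 kb from any called one. In the 118 others the ratio of H3K27me3 to Suz12 was 2.45 (1.62 to 3.78) and 2.54 (1.68 to 3.92) over these backgrounds, which argues against extra copies as the whole cause there. With every tag kept, the 28 windows were unlike the 4142 windows called for H3K27me3 and Suz12 only. Their ratio of H3K27me3 to Suz12 was 1.23 (1.04 to 1.34) against 3.38 (2.39 to 4.9). The 118 others overlap the range of the 4142 and cannot be told apart from it by this ratio. Ratios with 1 tag per position were not taken, and the contrast may depend on that choice. The chromosome 1 window had H3K27me3 at 476.4-fold and Suz12 at 236.3-fold with 1 tag per position. With every tag kept it had 832.7-fold and 622.9-fold. Adjoining regions of different kinds meeting in 1 window do not account for the 118, since 0.8% of them (1 window) touched both a run of H3K79me2 windows without H3K27me3 calls and a run of H3K27me3 windows without H3K79me2 calls, while both marks on the same DNA, on different alleles or in different cells stay open for all 146, as do extra copies as part of the cause.

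H3K27me3 and Suz12 tags were both slightly raised in H3K79me2 windows called in neither other library, 1.63-fold and 1.67-fold. Carry-over of H3K79me2 DNA would make the excess grow with the H3K79me2 excess over background. The latter rose 14.1-fold from the windows up to the lowest 10% cut of H3K79me2 tags to those from the highest 10% cut. With ties these groups held 6555 and 5079 windows. Between the same groups the excess rose only 2.12-fold for H3K27me3 (1.93 to 2.34) and 1.93-fold for Suz12 (1.81 to 2.06). These intervals come from resampling windows with replacement, which treats neighbouring windows as independent. A difference in mappability or copy number that reaches 6 to 10 kb beyond these windows is not the whole cause either. At 6 to 10 kb from a H3K79me2 window, the excess was 42.7% of that inside for H3K27me3 and 21% for Suz12. The distant windows include ones called for H3K27me3 or Suz12, which raise these values. H3K27me3 fell no further with distance, from 1.27-fold at 6 to 10 kb to 1.33-fold at 51 to 100 kb. A regional part of the cause stays open. So does mappability that differs from window to window, which this comparison cannot detect. The folds of both libraries were nearly equal (ratio 0.98, 0.971 to 0.989), which is consistent with an uneven background shared by both, such as chromatin that shears more easily. No biological explanation was tested.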
